A study of Homo sapiens with 4 samples.

How the data were processed

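DU145 cells were treated for 48 h with vehicle, No.10-3 at 5 µM, or C-30 at 0.5 or 2 µM, and total RNA was labelled with biotin by a whole-transcript kit, per the labels' protocols. Each condition has 1 array. Signals were made with Affymetrix Expression Console 1.3.0 and RMA, per the submitters' processing notes, and RMA as usually run corrects background, quantile-normalizes the arrays and summarises each probe set. The deposited values are log2 signals, a log base inferred from their range and from the usual output of RMA. The highest named value was 19.66, above the range that scanner readings span on a log2 scale, so the signals had probably been rescaled before summary, by a step not given in the sources used here, and a log2 difference of 1 is called 2-fold only on the scale of these values. Genome build and probe annotation of the processing are not given in the sources used here.

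Of 24351 probe sets, 17709 had 1 gene symbol in the platform annotation used, 0 had several and 6642 had none, of which 2903 were control probe sets. Symbols were updated by Entrez identifier, and all 17709 matched. They gave 17687 genes, and for the 20 genes with several probe sets the mean log2 value was taken. The arrays' deposited values were found in 2 tables that differed by at most 5e-05 once matched by probe set. Coordinates and genomic spans of genes come from a RefSeq table of GRCh38.p14.

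For each comparison the log2 difference between 2 arrays was taken per gene. A gene entered when the higher of the 2 values reached the median of all named probe sets over the 4 arrays, 5.56, and was counted at a log2 difference of at least 1 either way. The comparisons were each treated array with vehicle, the higher with the lower dose of C-30, and C-30 at 2 µM with No.10-3. With 1 array per condition no test, standard deviation or p-value is given, and the number of arrays limits the precision. The floor lies below the 95th percentile of the negative control probe sets, so genes near it can be within background.

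For 31 gene lists, of which 27 had at least 3 members past the floor in each comparison, the median difference is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. Lists under percentile 2.5 or over 97.5 are said to lie outside the band; the width of the band alone gives 1.35 of 27 per comparison, and simulated lists without an effect lay outside it more often (7.5% of 200). There were 10 such lists with No.10-3, and 1 and 5 with C-30 at 0.5 and 2 µM. The lists, the floor, the threshold, the comparisons and the rule for naming genes were chosen before the data were examined. That rule named the 12 highest and 12 lowest genes past the floor of each comparison with vehicle, the 6 highest and lowest of the other comparisons, the 4 members with the largest differences of each list outside the band, the 10 genes with the largest mean difference each way among those past 2-fold on all 3 treated arrays, and SFPQ, NONO and PSPC1. Uncharacterised loci, olfactory receptor, immune receptor segment and small RNA genes were left out of it. The lists of histone cluster genes and of replacement histone genes were added after seeing the data.

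Counts, and comparisons that share the vehicle array, were set beside 100 simulations of unchanged arrays, with array noise taken from the spread between the C-30 arrays. That spread includes any response to dose, but other pairs of arrays can be more or less noisy. The 63 ERCC probe sets had a robust SD of 0.152 between the C-30 doses. Against vehicle it was 0.126 with No.10-3, 0.166 with C-30 at 0.5 µM and 0.271 with C-30 at 2 µM. The noise was drawn from a normal distribution with a robust SD per level of signal, which leaves out heavy tails. The simulated counts and overlaps are therefore a guide, and neither a bound nor a chance level. Alternatives were a threshold of 1.5-fold, no floor, a floor at the 75th percentile (7.90), quantile normalization over named genes, a lowess correction of the difference on the mean signal (fraction 0.3), arrays centred on the median of genes past the floor, the brightest probe set of a gene, the other table of values, and random lists without matching. Counts without histone cluster genes, and random lists matched on genomic span as well, were added after seeing the data. The procedure was tested on simulated data for C-30 at 2 µM against vehicle over 9188 genes, with noise of the same kind. A 4-fold change passed 2-fold for 99.0% of 97 genes, a 2.8-fold change for 90.9% of 99 and no change for 1.85% of 8992. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.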

Results

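Gene expression was measured in DU145 cells, an established human prostate cancer line that grows without androgen, after 48 h with vehicle or with a compound described as an inhibitor of PSF. PSF is the protein product of SFPQ, a nuclear RNA-binding protein that takes part in splicing, in transcription and in paraspeckles, the nuclear bodies built on a long noncoding RNA. The 4 arrays held 1 array each of vehicle, No.10-3 at 5 µM, C-30 at 0.5 µM and C-30 at 2 µM. There were no replicates, so no difference has an error or a p-value, and all statements describe these 4 arrays. Genes are described as higher or lower by the log2 difference between 2 arrays and counted when they passed 2-fold, a log2 difference of 1 in either direction. The median signal of the 17687 named genes lay between 5.55 and 5.57 on the 4 arrays, and Pearson correlations between arrays across named genes lay between 0.979 and 0.987. The 95th percentile of the negative control probe sets lay between 7.06 and 7.32, and between 30.5% and 33.9% of genes had a signal above it. A gene under it on both arrays of a comparison is called within background, and the difference of a gene under this background level on 1 of them is inexact.

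The target gene was first examined, because an inhibitor of a protein need not alter its transcript. SFPQ (chromosome 1, 35176380 to 35193145 in GRCh38.p14) had a signal of 12.59 with vehicle, 12.61 with No.10-3, 12.60 with C-30 at 0.5 µM and 12.68 with C-30 at 2 µM, so it differed from vehicle by at most 0.09. NONO (chromosome X, 71283635 to 71301168), which encodes the usual dimer partner of PSF, was lower on each treated array, with differences of -0.31 for No.10-3, -0.66 for C-30 at 0.5 µM and -0.90 for C-30 at 2 µM, none of them past 2-fold. PSPC1 (chromosome 13, 19671205 to 19782945), the third member of this protein family, differed by -0.06, -0.03 and 0.06. Over the 12 measured genes of the PSF and paraspeckle list the median differences were 0.29, 0.09 and 0.08, within the middle 95% of random lists matched on expression. The only member past 2-fold was TARDBP on the array of C-30 at 0.5 µM, at 1.06, a gene picked out after its values were seen. Core spliceosome genes also stayed inside that band, with medians of 0.10, -0.12 and -0.10 over 28 genes, as did 5 measured androgen receptor target genes, at -0.03, -0.18 and -0.11. Of these 5, KLK3, PMEPA1 and NDRG1 were under the 95th percentile of the negative controls on each array, and the other 2 had medians of -0.14, -0.29 and -0.50.

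With No.10-3 at 5 µM, genes of mitosis were higher and genes of cholesterol and fatty acid synthesis were lower than with vehicle. The highest gene was CENPF, a kinetochore protein made in G2 and mitosis, at a log2 difference of 3.45 (10.9-fold), from 5.92 with vehicle to 9.37. The vehicle signal lay under the 95th percentile of the negative controls on that array, 7.32, so the fold is inexact. CCNB2, a mitotic cyclin, was higher by 1.99 and ANLN, which encodes a scaffold of the cytokinetic ring, by 1.88. TOP2A, the topoisomerase that untangles replicated chromosomes, was higher by 1.56. SREBF2, the transcription factor that drives sterol synthesis, differed by -1.76, and DHCR7, the enzyme of the last step to cholesterol, by -1.72. Among the lowest genes were also PTGES, the prostaglandin E synthase, at -2.18, the macrophage growth factor gene CSF1 at -1.97 and the immune checkpoint gene VSIR at -1.91. Others were the MAX partner MNT at -1.80 and IGFBP3, which encodes a binding protein of insulin-like growth factors, at -1.74.

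Of 34 measured genes of mitosis and G2/M, 32 were higher with No.10-3 and 8 of these passed 2-fold, and their median of 0.67 lay at percentile 100 of the matched random lists. Of 20 genes of cholesterol synthesis and uptake, 18 were lower and 5 passed 2-fold, with a median of -0.60 at percentile 0. MVD at -1.30 and HMGCS1 at -1.21, which encode enzymes of the mevalonate pathway, were among the 5, although MVD lay within background. The 9 genes of fatty acid synthesis had a median of -0.40 (percentile 0.44). SCD and FASN, the stearoyl-CoA desaturase and fatty acid synthase genes, were each at -1.31, their regulator SREBF1 at -0.90 and the desaturase gene FADS2 at -0.77. Chaperone genes of the unfolded protein response were lower in 15 of 19 cases (median -0.30, percentile 0.16), led by CRELD2 at -1.17, DNAJB11 at -0.85, SYVN1 at -0.84 and HERPUD1 at -0.67, of which CRELD2, the only member past 2-fold, lay within background. ATF4 targets of the integrated stress response were lower in 19 of 27 cases (median -0.28, percentile 0), with ATF3 at -1.11, CTH at -0.85 and DDIT4 at -0.72, whereas the cystine transporter gene SLC7A11 stood at 0.90. ATF3, the only member past 2-fold, and CTH lay within background. Inflammatory NF-kB genes were lower in 13 of 15 cases (median -0.29, percentile 0.745), with the cytokine gene LIF at -1.04, RELB, within background, at -0.90, TNFAIP3 at -0.68 and TNFAIP2 at -0.64.

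Another 4 lists lay outside the band with No.10-3. The 10 metallothionein and metal response genes had a median of -0.28 (percentile 2.24), with MT1E at -0.65, MT1B at -0.42 and MT1M at -0.33 against the zinc importer gene SLC39A10 at 0.42. That list lay inside the band with a floor at the 75th percentile (percentile 3.38), after quantile normalization (2.60) and beside random lists matched on span as well (5.15). Autophagy and lysosome genes went both ways, with ATG5 at 1.02 and BECN1 at 0.69 but GABARAPL1 at -0.73 and ULK1 at -0.62, and their median of -0.28 (percentile 0.705, 19 genes) stood beside a mean of -0.07 and lay inside the band after quantile normalization, at 5.28. ATG5 and ULK1 lay within background. The 11 measured genes of epithelial to mesenchymal transition, a list that holds markers of both states, had a median of 0.63 (percentile 99.9). In it the mesenchymal regulator ZEB1 at 1.29 and the keratin gene KRT19 at 0.93 were higher, and the tight junction gene CLDN4 at -1.63 and the integrin gene ITGA5 at -1.11 lower. Of the leukocyte markers, 3 were measured past the floor, where CD3E at -1.17 and CD79A at -1.14 had vehicle signals of 5.64 and 5.59, close to the floor of 5.56 and within background, and CD68 stood at 1.08. Without a floor the fatty acid list lay at percentile 5.88, the epithelial to mesenchymal list at 89.6 and the leukocyte list at 25.4, and a floor at the 75th percentile put the ATF4 targets at 7.45 and turned the leukocyte median to 1.08. Hybridization controls, labelled spikes of known amount, were lower on this array by log2 differences of -0.33, -0.39, -0.41 and -0.32 for bioB, bioC, bioD and cre. The dap, lys, phe and thr spikes were lower than vehicle on each treated array, by -0.34, -0.54, -0.28 and -0.34 with No.10-3, -0.35, -0.01, -0.21 and -0.80 with C-30 at 0.5 µM, and -0.50, -0.37, -0.42 and -0.89 with C-30 at 2 µM. The lys and phe spikes lay within background on every array, and lys hardly differed with C-30 at 0.5 µM. The thr spike was under the background level on the C-30 arrays, so its differences there are inexact.

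In all, 402 genes were at least 2-fold higher and 122 at least 2-fold lower with No.10-3 among 9219 genes past the floor, so that 76.7% of those past 2-fold were higher. Simulated unchanged arrays gave means of 71.6 higher and 71 lower. Their noise leaves out heavy tails, so here and below the simulated values are no chance level. Of the genes counted, 128 of the higher and 54 of the lower lay within background. Other highest genes were FAM171B at 2.60, the Holliday junction resolvase gene GEN1 at 2.57, the ubiquitin ligase gene WWP1 at 2.37, PUS7L at 2.28, MCTP1 at 2.20 and ZNF638 at 2.14. Next came the lipid kinase gene PIK3C2A at 2.09, the kinesin gene KIF5B at 2.04, the nuclear receptor corepressor gene NRIP1 at 2.01 and CCDC88A at 2.01. Within background were FAM171B, PUS7L, MCTP1 and ZNF638 of the 12 highest genes, and VSIR, MNT, KATNBL1, CLDN4, SUPT3H and SLC6A11 of the 12 lowest. CENPF, GEN1, WWP1, PIK3C2A, NRIP1 and CCDC88A, and of the list members SLC39A10, ZEB1 and GABARAPL1, were under the background level on 1 array and have inexact differences. The lowest genes not named above were KATNBL1 at -1.75, SUPT3H at -1.61, SLC6A11 at -1.48 and SKAP2 at -1.46. Part of the excess of higher genes went with the scaling. Centring each array on the median of its genes past the floor moved the median of all genes by -0.10 and left 59.1% of genes past 2-fold on the higher side, against 67.0% after quantile normalization and 70.4% after a correction for signal. Genes passed 2-fold upwards in 4.36% of cases and downwards in 1.32%. Together this is a smaller share than the 6.55% of positive control probe sets, counted without the floor, that passed 2-fold in either direction.

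**Figure D1:**
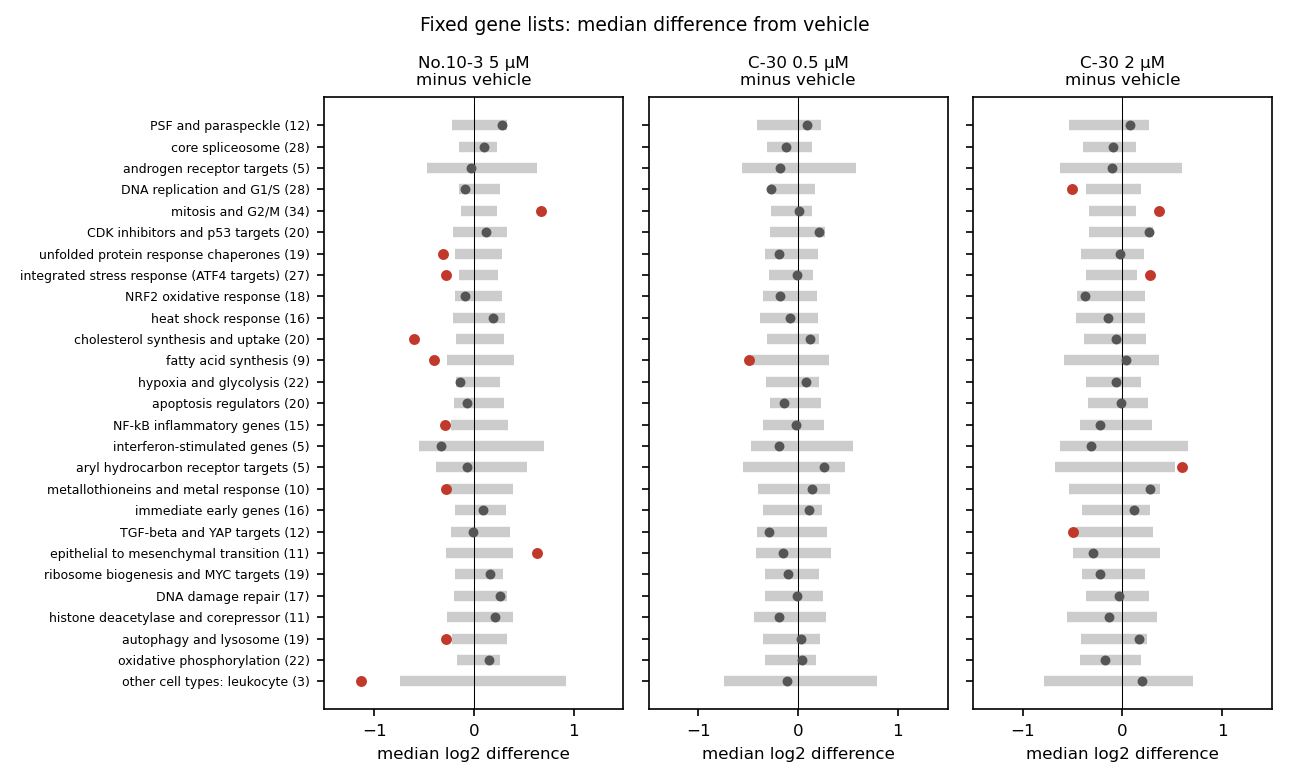
Median log2 difference from vehicle of the gene lists with at least 3 measured members, 1 panel per treated array, with the number of members in brackets. Points are list medians, grey bars the middle 95% of 10000 random lists matched on expression, and red points lie outside the bar; with No.10-3 the mitosis list lies at 0.67 and the cholesterol list at -0.60.

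With C-30 at 0.5 µM, replication-dependent histone genes were among the lowest genes and few fixed lists stood apart. H2BC14, a histone H2B gene, was the lowest gene at -2.07, followed among histones by H3C1 at -1.79, H3C8 at -1.77, H4C5 at -1.77 and H3C11 at -1.75. The highest genes were the chromatin remodeller gene CHD1 at 2.81, NRIP1 at 2.61, ANXA1, which encodes the anti-inflammatory protein annexin A1, at 2.52, and CENPF at 2.39. REV3L at 2.09 and POLK at 1.99 encode translesion DNA polymerase subunits, JMJD1C at 2.07 a demethylase-family protein, EIF3E at 2.06 a subunit of a translation initiation factor, and CXCL8 at 1.92 the chemokine interleukin-8. ZNF484 at 2.14, TBC1D19 at 2.13 and PIK3C2A at 1.90 were also among the highest. PRELID3A at -1.89, IQCK at -1.78, CMTM7 at -1.77, the retinoic acid receptor gene RARG at -1.73, the calpain gene CAPN1 at -1.72, the glycogen synthase gene GYS1 at -1.65 and C1QL1 at -1.60 were among the lowest. ZNF484, TBC1D19, REV3L, PRELID3A and IQCK lay within background. CHD1, NRIP1, CENPF, JMJD1C, POLK, CXCL8, PIK3C2A, CMTM7, H4C5 and RARG were under the background level on 1 array, so their differences and ranks are inexact.

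Histone genes were not among the lists chosen before the data were examined, and the list of histone cluster genes was drawn up by symbol after their differences had been seen. All 53 measured histone cluster genes were lower with C-30 at 0.5 µM, 32 of them past 2-fold, with a median of -1.08. Of the 53, 7 lay within background, 2 of these past 2-fold. Of the fixed lists, only fatty acid synthesis lay outside the band, at -0.50 over 9 genes (percentile 1.65, or 6.98 without a floor), with SREBF1 at -0.88, FASN at -0.71, ACSS2 at -0.71 and FADS2 at -0.64. Mitosis genes had a median of 0.01 over 34 genes, cholesterol genes 0.12 over 20 and ATF4 targets -0.01 over 27. Genes of DNA replication and the G1/S transition had a median of -0.28 over 29 genes, at percentile 2.91, or 2.20 of random lists without matching. In total 315 genes were at least 2-fold higher and 257 lower among 9267 past the floor, with 99 and 76 of these within background and simulated means of 70.5 and 71.2, and 8.06% of positive control probe sets passed 2-fold in either direction.

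With C-30 at 2 µM, the replication-dependent histone genes made up the lowest end of all genes measured. The 12 lowest genes were all of this family and began with H2BC14 at -5.63 (49.6-fold lower, from 13.23 with vehicle to 7.59), H3C8 at -4.57, H3C11 at -4.32 and the linker histone gene H1-5 at -3.98. After these came H2BC10 at -3.86, H2AC8 at -3.83, H2AC4 at -3.74, H2BC13 at -3.72, H4C14 at -3.41, H2BC11 at -3.33, H2BC8 at -3.32 and H3C10 at -3.30. All 53 measured histone cluster genes were lower and 48 passed 2-fold, with a median of -2.27, below all 10000 matched random lists. Of the 53, 7 lay within background, 2 of these past 2-fold, and the other 46 had a median of -2.59. Some of the 46 were under the background level on 1 array and have inexact differences. By family the medians were -1.89 for H1 (6 genes), -2.13 for H2A (13), -2.71 for H2B (16), -2.94 for H3 (7) and -2.26 for H4 (11). With No.10-3 the same 53 genes had a median of -0.21, also below all matched random lists, with 42 of them lower. H2BC14 alone passed 2-fold there, at -1.07. The list was drawn up after its members were seen to be low against this vehicle array, which enters both differences. Neither rank among random lists is therefore independent support for an effect. The 6 replacement histone genes, which are also transcribed outside S phase, had a median of -0.45 with C-30 at 2 µM, at percentile 11.5. Histone cluster genes are near-identical copies, so values of single members are uncertain where probes could read more than 1 of them.

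**Figure D2:**
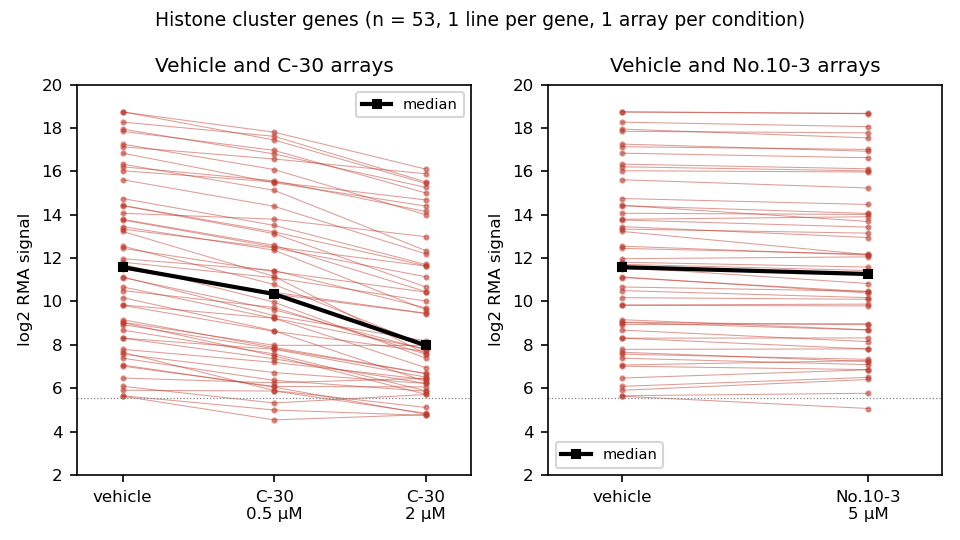
Log2 signal of 53 histone cluster genes, 1 line per gene and 1 array per condition, with vehicle and both C-30 doses on the left and vehicle and No.10-3 on the right. The black line joins the medians and the dotted line is the floor of 5.56; the median difference from vehicle was -1.08 at 0.5 µM, -2.27 at 2 µM and -0.21 with No.10-3.

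Genes of DNA replication and the G1/S transition were also lower with C-30 at 2 µM, in 23 of 28 cases with 7 past 2-fold (median -0.51, percentile 0.11). They included the replicative helicase genes MCM5 at -1.54 and MCM4 at -1.17, the cyclin gene CCNE2 at -1.46 and CDC45, which encodes a partner of that helicase, at -1.13. Mitosis genes stood on the other side, higher in 25 of 34 cases (median 0.37, percentile 100), with CENPF at 2.07, CCNB2 at 1.70 and CDK1, the mitotic kinase gene, at 1.61, against the kinetochore gene NUF2 at -1.36. CCNE2 and NUF2 lay within background. ATF4 targets of the integrated stress response were higher in 18 of 27 cases (median 0.28, percentile 99.8), with the stress transcription factor genes ATF3 at 2.16 and DDIT3 at 1.40, SLC7A11 at 1.52 and the asparagine synthetase gene ASNS at 0.95. TGF-beta and YAP targets were lower in 11 of 13 cases (median -0.49, percentile 1.73), with the differentiation inhibitor genes ID1 at -1.98 and ID3 at -1.67, CCN1 at -1.63 and ANKRD1 at -1.19. That list lay inside the band under 5 of the other settings tried, at percentile 4.18 after a correction for signal. The 5 measured aryl hydrocarbon receptor targets had a median of 0.60 (percentile 98.5), with TIPARP at 0.79, CYP1B1 at 0.63 and CYP1A1 at 0.60 but NQO1 at -0.29. CYP1B1 and CYP1A1, whose own difference is the list median, lay within background, and the median of the other 3 members was -0.13. That list was also inside the band under 5 of the other settings: without a floor (percentile 92.1), after quantile normalization (96.7), after a correction for signal (96.6), without matching (97.4), and with a floor at the 75th percentile, which also turned the median to -0.13.

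The highest genes with C-30 at 2 µM were ANXA1 at 2.76, IDI1, the isopentenyl diphosphate isomerase gene of sterol synthesis, at 2.62, CXCL8 at 2.46, the protein kinase D gene PRKD3 at 2.39 and ATF3. The list went on with ZZZ3 at 2.13, CENPF, ESF1 at 1.99, VPS36 at 1.95, the splicing factor gene CDC40 at 1.95, LARP7 at 1.93 and CCDC73 at 1.92, of which ESF1, LARP7 and CCDC73 lay within background. CXCL8, PRKD3, ATF3, ZZZ3, CENPF and VPS36 were under the background level on 1 array, as were GADD45A, DDB2, DDIT3 and ANKRD1 of the lists and H2BC10, H2BC13 and H3C10 of the lowest genes, so their differences are inexact. Cholesterol genes as a list had a median of -0.06 over 20 genes (percentile 54.3), with members such as IDI1 and HMGCS1 at 1.34 higher and others such as TM7SF2 at -1.46 lower. With a floor at the 75th percentile that median was 0.40, outside the band at percentile 99.4. Genes of CDK inhibitors and p53 targets had a median of 0.27 over 20 genes, inside the band at percentile 96.2. Under 4 of the other settings it lay outside, at up to percentile 98.7 beside random lists matched on span as well. Its members past 2-fold, picked out after their values were seen, were GADD45A at 1.73, CDKN1B at 1.22, RRM2B at 1.16 and DDB2 at 1.04 on the higher side and TIGAR at -1.04 on the lower, of which RRM2B and TIGAR lay within background. In total 435 genes were at least 2-fold higher and 573 lower among 9319 past the floor, with 148 and 138 of these within background and simulated means of 70.6 and 70.6, and 525 were lower without the histone cluster genes. The share on the higher side was 43.2%, or 52.3% after quantile normalization, 49.9% after a correction for signal and 55.1% with arrays centred on their medians. Genes passed 2-fold upwards in 4.67% of cases and downwards in 6.15%. Together this is slightly under the 11.3% of positive control probe sets past 2-fold in either direction.

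Between the C-30 doses, histone genes were again the lowest group at 2 µM compared with 0.5 µM, with H2BC14 at -3.56, H3C8 at -2.80, H1-5 at -2.78, H2AC8 at -2.74, H3C11 at -2.57 and H2AC4 at -2.45. The median over 51 histone cluster genes was -1.33, with 49 lower and 35 past 2-fold. Of the 51, 8 lay within background, 2 of these past 2-fold. Of the 53 genes measured against vehicle, 50 (94.3%) were ordered vehicle above 0.5 µM above 2 µM, in a list drawn up after its members had been seen to be low on these arrays. Genes of DNA replication and G1/S were lower in 23 of 29 cases (median -0.35, percentile 0.025), with MCM10 at -0.98, CCNE2 at -0.88, the clamp loader gene RFC3 at -0.73 and CDC6 at -0.63, of which MCM10 and CCNE2 lay within background. ATF4 targets were higher in 23 of 27 cases (median 0.32, percentile 100), with ATF3 at 1.99, SESN2 at 1.27, DDIT3 at 1.25 and PPP1R15A at 0.79. Mitosis genes were higher in 24 of 34 cases (median 0.20, percentile 99.9), with KIF2C at 1.60, CCNB1 at 1.34 and HMMR, within background, at 1.26 against NUF2 at -1.79. The highest single genes were KLHL28 at 2.27, ZNF345 at 2.15, the endoplasmic reticulum protein gene ERLIN2 at 2.07, ATF3, the homeobox gene HHEX at 1.80 and TRIM38 at 1.67, of which KLHL28, ZNF345 and TRIM38 lay within background. ERLIN2, HHEX, DDIT3, PPP1R15A and NUF2 were under the background level on 1 array and have inexact differences. At 2 µM, 129 genes were at least 2-fold higher and 202 lower than at 0.5 µM, among 9282 past the floor, with 70 and 79 of these within background. The simulated means were 71.0 and 71.5, with noise taken from the robust spread of this same pair of arrays. As that spread leaves out the tails, the excess over these means is no measure of a response to dose.

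Set side by side, the compounds differed in histone, sterol and stress genes, although the doses were not matched (2 µM of C-30 against 5 µM of No.10-3) and no interval of the difference can be given. ATF3 was higher with C-30 by 3.27, IDI1 by 2.73 and HMGCS1 by 2.55. The difference of ATF3 is inexact, as its signal with No.10-3, 6.13, lay under the 95th percentile of the negative controls. Next came the gamma-tubulin complex gene TUBGCP6 at 2.23, SPANXD at 2.12 and GDF2 at 2.01, of which GDF2 reached a signal of only 5.92, within background, and the others were under the background level on 1 array. Cholesterol genes were higher with C-30 in 16 of 20 cases, 8 past 2-fold (median 0.78, percentile 100), including MSMO1 at 1.86 and DHCR7 at 1.65. ATF4 targets were higher in 22 of 27 cases (median 0.39, percentile 100), with DDIT3 at 1.73, SESN2 also past 2-fold and CHAC1 at 0.96, and the difference of DDIT3 is inexact in the same way. Unfolded protein response chaperones were higher in 12 of 18 cases (median 0.17, percentile 99.3), with DNAJB9 at 1.08, HERPUD1 at 0.99, DNAJB11 at 0.84 and DNAJC3 at 0.50, of which DNAJB9 and DNAJC3 have inexact differences. Metallothionein genes were higher in 8 of 10 cases (median 0.49, percentile 99.9), with MT1B at 0.83, MT1F at 0.79 and MT2A at 0.72 but the zinc exporter gene SLC30A1 at -0.75, of which MT1F and SLC30A1 lay within background.

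**Figure D3:**
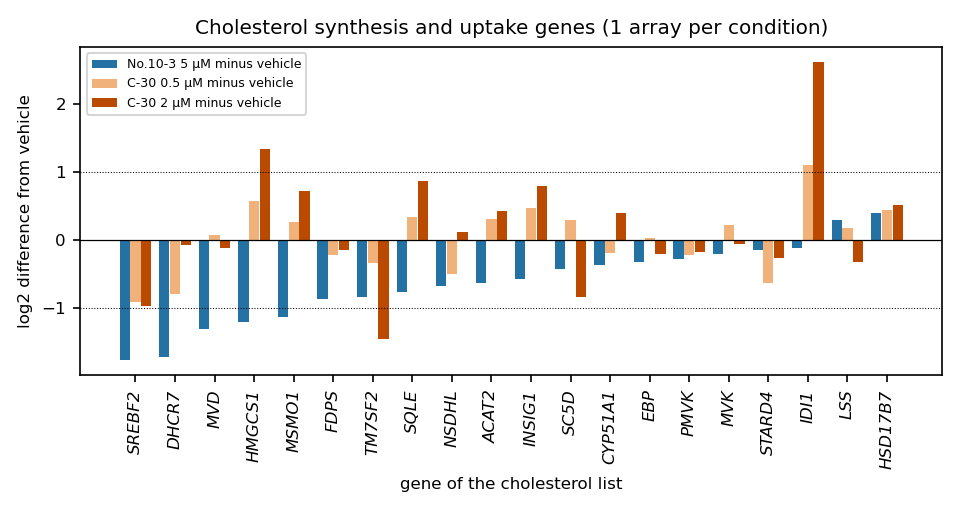
Log2 difference from vehicle of 20 cholesterol synthesis and uptake genes, 3 bars per gene, 1 for each treated array, with dotted lines at 2-fold. With No.10-3, SREBF2 stands at -1.76 and DHCR7 at -1.72, and with C-30 at 2 µM, IDI1 stands at 2.62 and HMGCS1 at 1.34.

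Lower with C-30 at 2 µM than with No.10-3 were 52 of 52 histone cluster genes (median -2.16, 48 past 2-fold), led by H2BC14 at -4.56, H3C8 at -4.15, H3C11 at -4.03, H2BC10 at -3.79, H1-5 at -3.77 and H2BC13 at -3.52, of which H2BC10 and H2BC13 have inexact differences. Of the 52, 5 lay within background, 2 of these past 2-fold. Genes of DNA replication and G1/S were lower in 24 of 28 cases (median -0.50, percentile 0.2), with MCM5 at -1.31, the licensing factor gene CDT1 at -1.17, MCM6 at -1.06 and the thymidine kinase gene TK1 at -0.92. CDT1 lay within background, and a floor at the 75th percentile put the list inside the band, at percentile 6.10. Mitosis genes, whose medians lay above vehicle on both of these arrays, were lower with C-30 than with No.10-3 in 25 of 34 cases (median -0.48, percentile 0.31), with the proliferation marker gene MKI67 at -1.47, CENPF at -1.38, TOP2A at -1.36 and NUF2, within background, at -1.21. TGF-beta and YAP targets had a median of -0.55 over 13 genes (percentile 1.16), with ID1 at -1.94, CCN1 at -1.71, ID3 at -1.63 and THBS1 at -1.07. That list lay at percentile 14.8 without a floor. The 3 leukocyte markers past the floor had a median of 1.19, with CD79A at 1.33 and CD3E at 1.19, both within background, and CD68 at -0.71. That median lay inside the band without a floor (percentile 83.5) and after a correction for signal (78.4), and a floor at the 75th percentile turned it to -0.71. In this comparison 225 genes were at least 2-fold higher and 524 lower among 9311, with 106 and 123 of these within background and simulated means of 70.7 and 70.8, so 30.04% lay on the higher side. Other scalings moved the median of all genes by 0.13 (quantile), 0.12 (correction for signal) and 0.17 (centring), and left 48.5%, 44.3% and 59.4% on the higher side.

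A group of genes differed from vehicle in the same direction on all 3 treated arrays. At least 2-fold higher on each were 87 genes, and at least 2-fold lower 22, where 100 simulations of unchanged arrays against the 1 vehicle array gave means of 2.45 and 2.65 and at most 8 and 7. Of the 87 and the 22, 21 and 4 lay within background on all 4 arrays, MCTP1 and VSIR among them, and GEN1 and PRKD3 were within background in 2 of the 3 comparisons. Among the higher genes were CENPF, ANXA1 (1.90, 2.52 and 2.76 for No.10-3, C-30 at 0.5 µM and C-30 at 2 µM), NRIP1 (2.01, 2.61 and 1.65), GEN1 (2.57, 1.79 and 1.73) and CHD1 (1.48, 2.81 and 1.56). Others were MCTP1 (2.20, 1.76 and 1.82), WWP1 (2.37, 1.62 and 1.51), ZZZ3 (1.62, 1.70 and 2.13), PRKD3 (1.94, 1.06 and 2.39) and PIK3C2A (2.09, 1.90 and 1.32). Of these 10, all but ANXA1 were under the background level on at least 1 array of each comparison, so their differences are inexact. Among the lower genes were H2BC14, VSIR (-1.91, -1.21 and -1.77), GYS1 (-1.41, -1.65 and -1.81), PTGES (-2.18, -1.23 and -1.46) and CSF1 (-1.97, -1.19 and -1.52). The others named were RARG (-1.05, -1.73 and -1.88), the tubulin gene TUBA4A (-1.10, -1.30 and -2.12), C1QL1 (-1.23, -1.60 and -1.46), ITGA5 (-1.11, -1.60 and -1.47) and ALDH3B1 (-1.14, -1.45 and -1.41). The higher genes were mostly genes of long genomic span. With all genes cut by span into 5 groups of equal size, they made up 0.0519% of the group with the shortest spans and 1.71% of the group with the longest. As the vehicle array enters all 3 differences, a reading of that array alone can place genes in this group.

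Across the 9630 genes past the floor on any array, differences from vehicle with No.10-3 and with C-30 at 2 µM had a Pearson correlation of 0.51 and a Spearman correlation of 0.50 across genes, which are not independent replicates. Unchanged arrays simulated against the shared vehicle array gave a Pearson correlation of 0.50. The covariance was 0.164 against 0.0824 in the simulations, a difference of 0.0815. Both differences passed 2-fold upwards for 133 genes and downwards for 41, where the simulations gave means of 7.96 and 9.42 and at most 18 and 18. For the C-30 doses the Pearson correlation was 0.71 and the Spearman correlation 0.70, with a covariance of 0.239 against 0.0821, a difference of 0.157. There the 2 arrays shared 145 higher genes and 147 lower genes, against simulated means of 7.85 and 9.4. For No.10-3 and C-30 at 0.5 µM, a pair reported after its values were seen, the Pearson correlation was 0.59 and the Spearman correlation 0.54, with a covariance of 0.156 against 0.0824, a difference of 0.0731. That pair shared 145 higher genes and 27 lower genes, against simulated means of 8.21 and 9.78 and at most 16 and 19. In part or in whole, the excesses of the pairs with No.10-3 may come from the vehicle array, which could not be split. The larger excess of the C-30 doses may come from it in part. The difference of No.10-3 from vehicle and that between the C-30 doses, which share no array, had a Pearson correlation of 0.04 and a Spearman correlation of 0.05.

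**Figure D4:**
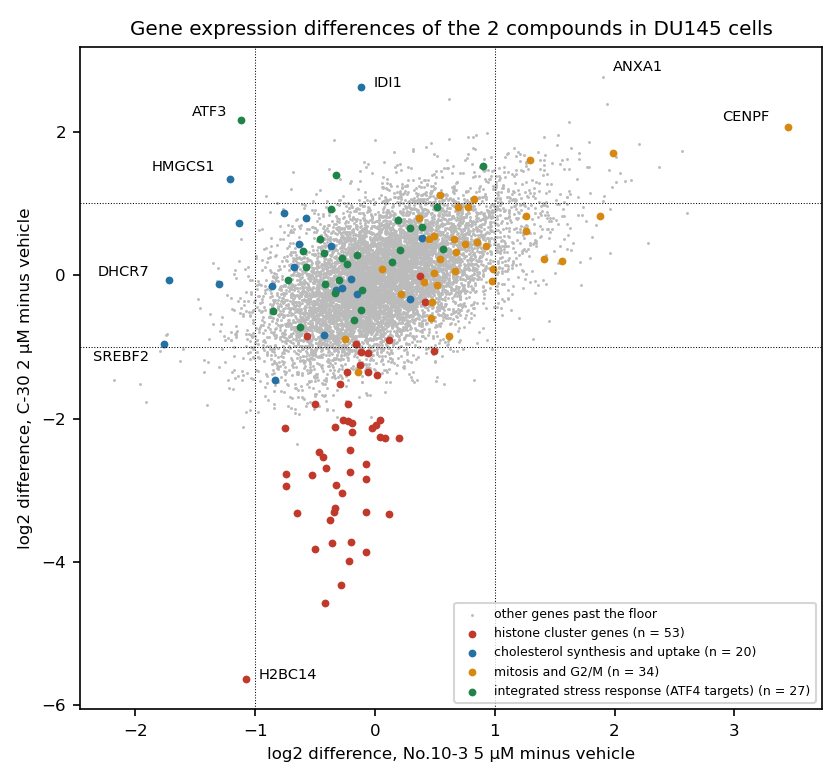
Log2 difference from vehicle with C-30 at 2 µM against that with No.10-3, 1 point per gene past the floor, with 4 gene groups coloured and dotted lines at 2-fold. Histone cluster genes spread downwards to -5.63 (H2BC14) and lie closer to 0 on the No.10-3 axis (H2BC14 at -1.07), and CENPF lies at 3.45 and 2.07.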

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

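Probe sets without a gene name entered no comparison above, and some of them differed from vehicle by 2-fold or more. Of 3739 such probe sets other than controls, 1560 lay past the floor with No.10-3, 1585 with C-30 at 0.5 µM and 1603 at 2 µM. Of those past the floor, 54, 57 and 71 were at least 2-fold higher, and 33, 39 and 89 at least 2-fold lower. Past the floor, 5.58%, 6.06% and 9.98% of them passed 2-fold in either direction, beside 6.55%, 8.06% and 11.3% of the positive control probe sets. No explanation was tested, and with 1 array per condition the counts have no error.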

How the results depend on the processing

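Counts without histone cluster genes, percentiles matched on genomic span and the correlation of No.10-3 with C-30 at 0.5 µM were chosen after seeing the data. No paired analysis was possible because each condition has 1 array. Of 90 counts under other settings, 63 stayed within 1.5 times the reported count and 27 did not. At 1.5-fold the counts, higher then lower, were 1362 and 769 for No.10-3, 1128 and 1242 for C-30 at 0.5 µM, 1405 and 1720 for C-30 at 2 µM, 732 and 921 between the doses, and 933 and 1870 between the compounds. With the floor at the 75th percentile, where fewer genes enter, they were 202 and 51, 156 and 153, 209 and 377, 37 and 88, and 83 and 308. Without a floor, where more enter, 189 genes were lower with No.10-3, 213 higher between the doses and 387 higher between the compounds. Centring left 192 lower with No.10-3, and 447 higher and 306 lower between the compounds, where quantile normalization gave 338 higher, and the cause was not tested. The correlation of No.10-3 with the dose difference was 0.0178 without a floor and 0.0755 at the 75th percentile, and the other 26 correlations moved little. Of 1259 list medians, 1216 kept their side of the band, 22 moved inside it, 18 moved outside, and 3 reversed and moved inside as well. The sign differed for 86, namely 81 of the 1216, 2 of the 18 and the 3 reversed. The 3 reversed, all at the 75th percentile floor, where fewer members enter, were leukocyte markers with No.10-3 (1.08) and between the compounds (-0.71), and aryl hydrocarbon receptor targets with C-30 at 2 µM (-0.13). Under 9 settings the histone median with C-30 at 2 µM lay between -2.72 and -2.14, the mitosis median with No.10-3 between 0.57 and 0.72, and the cholesterol median with No.10-3 between -0.72 and -0.60. Of 1210 differences of named genes, 1178 kept their side of 2-fold, 20 passed it and 12 dropped under it. The sign differed for 5, 3 of SFPQ with No.10-3 and 2 of PSPC1 with C-30 at 0.5 µM, none of them past 2-fold. Signal over background is a limit, as 27.1% to 32.4% of 612 negative control probe sets differed from vehicle by 2-fold or more.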

Other observations

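Tests of the span trend, of the vehicle reading for genes higher on all 3 arrays, of the signal trend for cholesterol genes and of long genes were chosen before their results were seen. Those of histone genes, and of the vehicle reading for cholesterol genes, were chosen after. Members named in the paragraph on further gene groups were also picked after their values were seen.

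Further gene groups stayed inside the band of random lists while single members passed 2-fold. Among 16 heat shock genes, HSP90AA1, the inducible cytosolic HSP90 gene, stood at 1.42, 1.79 and 1.68 with No.10-3, C-30 at 0.5 µM and C-30 at 2 µM, and the mitochondrial chaperonin gene HSPD1 at 1.03, 0.91 and 1.01, whereas the list medians were 0.20, -0.08 and -0.15. The HSP90 cofactor gene CHORDC1 stood at 1.25 and 1.42 on the C-30 arrays, and the small heat shock gene HSPB1 at -1.01 with C-30 at 2 µM. The DNA damage kinase gene ATM stood at 1.28, 1.59 and 1.10, the helicase gene BLM was past 2-fold higher with No.10-3 but within background, and the exonuclease gene EXO1 was at -1.51 with C-30 at 2 µM. Immediate early genes EGR1 and JUN stood at 1.47 and 1.17 with C-30 at 2 µM, and EGR1 at 1.22 with No.10-3. With C-30 at 2 µM the BH3-only gene PMAIP1, within background, stood at 1.22. The growth-linked genes SRM, of polyamine synthesis, and CAD, of pyrimidine synthesis, stood there at -1.46 and -1.26. In either direction, 2 apoptosis regulators and 4 ribosome biogenesis and MYC targets passed 2-fold on that array, and 4 heat shock genes with No.10-3, not all named here.

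Histone cluster genes were lower with C-30 at 2 µM. All 5 families had medians of -1 or below at 2 µM, so the pattern was not confined to 1 family. Shared readings of near-identical copies within each of the 5 families would give such medians too, so cross-hybridization is not excluded. A trend of the difference with signal was argued against as the whole cause, since the median after that correction was -2.28. The G1/S list, with a median of -0.51, had what fewer cells in S phase would need, so a smaller share of S-phase cells with C-30 may be part of the pattern, as a hypothesis. An array of C-30 at 2 µM that reads these genes low for other reasons would not lower them at 0.5 µM. There the median lay between -1.16 and -1.03 under 9 settings, which reprocess the same arrays, with 32 of 53 past 2-fold. These values argue against a reading of the 2 µM array alone as the whole cause. They are no independent support for an effect, since the list was drawn up after its members were seen to be low. The vehicle array also enters both differences. Whether the further drop at 2 µM is a graded response to dose or a reading of that array is left open. Each dose has 1 array, and the 50 of 53 members in dose order belong to a list drawn up after they were seen to be low. Histone mRNA made or kept at a lower level within S-phase cells remains open, because no value here counts cells by phase.

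Cholesterol genes were lower with No.10-3 and not with C-30 at 2 µM. A trend with signal was argued against as the whole cause, as the median after that correction was -0.68. A difference between the compounds, between their doses, or in the No.10-3 array by itself may each account for it, and the design does not separate these. A high reading of the vehicle array alone would lower this list on all 3 treated arrays. Under 9 settings the list median lay between 0.12 and 0.20 with C-30 at 0.5 µM and between -0.06 and 0.40 at 2 µM. The value at 2 µM is part of the pattern, so it cannot test such a reading. The value at 0.5 µM, from 1 array, argues against such a reading as the whole cause, unless C-30 raised the list there by about as much. The median between the compounds, 0.78, leaves the vehicle array out but follows from the pattern itself.

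Genes at least 2-fold higher on all 3 treated arrays went with genomic span. With genes cut by span into 5 groups of equal size, they made up 0.0519% of the shortest group, against 0.903% of all genes. This is an association and does not test span as a cause. Medians of the longest and shortest groups differed by 0.24, 0.13 and 0.13 on the treated arrays. A trend of that size falls well short of a log2 difference of 1. The trend with span could be technical or biological, and no RNA quality value was analysed here. A vehicle array that stands apart for these genes cannot be told apart from a response already complete at 0.5 µM, since the median of 85 of them between the C-30 doses was -0.0557, at percentile 34.5. Each array in turn was counted as the one that stands apart. By 2-fold, 87 genes were lowest on the vehicle array, 84 on that of C-30 at 2 µM, 9 at 0.5 µM and 8 with No.10-3. Up to 35 of the 84 can be histone cluster genes, the number past 2-fold lower at 2 µM than at 0.5 µM. Highest by 2-fold were 22 genes on the vehicle array, 31 with C-30 at 2 µM, 5 at 0.5 µM and 32 with No.10-3.

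PSF might sustain transcription of long genes, in which case its inhibitors would lower them. The median of the group with the longest spans lay above that of the group with the shortest on each treated array, by 0.24 with No.10-3, 0.13 with C-30 at 0.5 µM and 0.13 with C-30 at 2 µM (smallest difference 0.125). These differences share the vehicle array, so a span trend of that array alone would raise all 3. Between the C-30 doses, where it is left out, the difference was -0.0308 with a Spearman correlation of -0.02. Between C-30 at 2 µM and No.10-3, where it is left out too, they were -0.14 and -0.09. A span trend of the vehicle array alone therefore leaves the larger value with No.10-3 unexplained. The hypothesis is therefore neither excluded nor favoured. Spearman correlations of the difference from vehicle with span across genes were 0.18, 0.10 and 0.07.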
